A study of Mus musculus with 162 samples.

How the data were processed

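RNA of 162 single cells from mouse embryos at E17.5 to E18.5 was sequenced, each from cytosol drawn into a patch-clamp pipette, by the labels as total RNA with a standard Illumina library protocol. Per the submitters' processing notes, Trimmomatic, STAR and featureCounts were used with build GRCm38; no version is given. The authors deposited counts, whole-number reads per gene and cell, once by Ensembl identifier and once by gene symbol. They also deposited a normalized signal table of the 148 passed cells and 22800 genes, in which 99.8% of values lay within 0.1% of the counts divided by 1 factor per cell; how the authors set that factor is not stated. The table by Ensembl identifier held 22880 rows, of which 22570 were given a symbol from GENCODE M21 and 310 were not; summing identifiers of the same symbol left 22879 genes. The table by symbol was held only in part, so the Ensembl table was used throughout and the other as an alternative, the reverse of what was planned; 8972 of 8990 shared symbols (99.8%) had equal counts in all cells. No 2 cells had identical counts. Ribosomal RNA genes took a median of 0.497% of a passed cell's counts (highest 7.32%).

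Groups were taken from the submitters' type, driver line and quality labels only. Comparisons, gene lists, the naming rule and all alternatives but 4 were chosen before the data were examined. They were: cells of the MGE-derived, CGE-derived and GABAergic labels against both Glutamatergic labels, MGE-derived against CGE-derived, MGE-derived 1 against 2, Glutamatergic 1 against 2, Cajal Retzius against Glutamatergic, VZ-derived against Glutamatergic, the Lhx6 against the Htr3a line among MGE-derived cells, the Nex against the Htr3a line among Glutamatergic 1 cells, failed against passed cells, and type labels by line. Since no label names an animal, litter or culture, each group counts as 1 sample and no test of a difference between groups, p-value or count of changed genes was computed. The driver line goes with the animals and no label names a batch, so line, animals and batch cannot be separated. Values within the Htr3a line are given where they differ. Counts were divided by each cell's total (CPM); the difference is that of the mean over cells of log2(CPM + 1). Beside it stand the CPM of summed counts with exact Poisson 95% intervals and shares of cells with exact Clopper-Pearson 95% intervals. Single cells far from their group were marked by Dixon's 95% critical value. Intervals of CPM are printed where a group held few counts and for Nrxn3 of the comparison of GABAergic with glutamatergic cells; elsewhere they are narrow and are left out. A fold against a group with 0 counts is a lower bound computed against 3 counts over the group. Where no cell of a line had a label, the upper limit of its share is 3 cells over the cells of the line.

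Genes were named by a rule: a count in at least 50% of cells of the higher group, at least 20 CPM there, at least 2-fold by summed counts and by mean CPM, at least 2-fold without the cell of highest level, and of those the 10 with the largest difference in each direction. The neurexins, the 3 driver genes and up to 4 members per list with the largest difference were named as well, some genes are not reported here, and any other gene is said to be chosen after its values were seen. The 26 gene lists cover neurexins, neurexin ligands and partners, RNA-binding splicing regulators, other synaptic adhesion molecules, pan-neuronal, glutamatergic, GABAergic, MGE and CGE interneuron, Cajal-Retzius cell, ventricular zone progenitor and intermediate progenitor markers, proliferation, upper and deep layer genes, astrocyte, oligodendrocyte lineage, microglia, endothelial and mural cell markers, erythrocyte genes, ionotropic glutamate receptors, GABA-A receptors and chloride transporters, voltage-gated channels, presynaptic release genes, migration and guidance receptors, and immediate early and heat shock genes. A list member was counted where at least 10% of the cells of either group held a count, and called higher or lower where its log2 difference was at least 1. The median of a list was placed among 10000 random lists matched on mean expression in 50 bins, as a description and not a test.

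The comparisons were tested on simulated data made from the counts, with 2-, 4-, 8- and 16-fold differences added to 50 genes each. For GABAergic against glutamatergic cells 76%, 90%, 96% and 100% of these genes had the right direction, and for the Nex against the Htr3a line 54%, 70%, 72% and 84%. Of genes with no difference 7.59% and 34.6% passed a difference of 1 in these 2 comparisons, and the largest such values are given beside the named genes. Those values are of genes that met the naming rule below or above 0, apart from its condition on the cell of highest level. Cells were shuffled within each gene, so simulated groups did not carry the real difference in genes per cell. Single cells were the units of the shuffling, so these values are a description and not a test. Alternatives were the authors' normalized table, edgeR effective library sizes (TMM with singleton pairing), a pseudocount of 10, no filter on list members, cells thinned to 4563756 counts (the 5th percentile; 8 of 148 passed cells left out), summed counts, mean CPM, single driver lines, failed cells added, each cell left out in turn, the GABAergic or Undefined label left out, all other typed cells as the comparison group, the table by symbol, and genes of other lists left out. Added after the data were seen were cells with like numbers of genes, Htr3a line cells with microglia genes left out, ribosomal RNA left out, and 10 counts per cell for detection. Sequence shared between genes was measured as the share of a gene's 50-base stretches that occur in transcripts of another gene of GENCODE M21. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.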

Results

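RNA of single cells from mouse embryos at E17.5 to E18.5 was read by sequencing. The cytosol of each cell was drawn into a patch-clamp pipette, so each of the 162 samples is 1 cell. The cells came from 3 Cre driver lines, named for genes whose promoters mark classes of cortical neurons: 122 from the Htr3a line (a serotonin receptor gene of interneurons), 22 from the Lhx6 line (a transcription factor gene of interneurons) and 18 from the Nex line (Neurod6, a gene of glutamatergic neurons). The submitters passed 148 cells in quality control and failed 14. Passed cells held 1710224 to 24836041 counts (median 9463972.5) in 2066 to 14810 genes (median 5363). The submitters gave the passed cells 9 type labels: 18 MGE-derived 1, 24 MGE-derived 2, 11 CGE-derived, 4 GABAergic, 33 Glutamatergic 1, 13 Glutamatergic 2, 12 Cajal Retzius, 11 VZ-derived and 22 Undefined. The labels do not spell out MGE, CGE and VZ; the gene lists took them as the medial and caudal ganglionic eminences and the ventricular zone.

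No label names an animal, litter or culture, so each group counts as 1 sample, there are no replicates, and no difference was tested. Values are CPM of a group's summed counts, each gene's share of the counts on a common scale, differences of the mean over cells of log2(CPM + 1) (called log2 differences below) with the SD between cells, and shares of cells with a count. All 95% intervals cover counting error at most. Those of CPM are too narrow even for that, since reads without molecular identifiers are not independent molecules. The type labels probably rest on the same cells' expression, so marker genes of a label are not independent evidence of it.

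The series concerns neurexins, presynaptic adhesion proteins whose transcripts are spliced in many forms; splice forms were not analysed here, only the level of each gene. Nrxn3 was high in the interneuron types, at 509 CPM in MGE-derived 2 cells (24 of 24 cells with a count), 466 in CGE-derived cells (11 of 11), 294 in GABAergic cells (4 of 4) and 288 in MGE-derived 1 cells (15 of 18). It was low in Glutamatergic 1 cells (44.3 CPM), Glutamatergic 2 cells (60.7) and VZ-derived cells (18.1). In Cajal Retzius cells, the early born neurons of the cortical surface, it was almost undetected, at 0.0898 CPM (95% interval 0.0491 to 0.151) with a count in 2 of 12 cells. Levels of Nrxn2 were 93.2 CPM in VZ-derived, 67.6 in MGE-derived 1, 54.8 in MGE-derived 2, 34.3 in GABAergic, 22.2 in Glutamatergic 1, 17.6 in CGE-derived, 13.3 in Glutamatergic 2 and 5.72 in Cajal Retzius cells. Single cells carried much of several of these levels. Without the cell of most counts Nrxn3 stood at 3.62 CPM in VZ-derived and 156 in GABAergic cells, and in Cajal Retzius cells 12 of the 14 counts came from cell 7, which leaves 2 counts (0.0134 CPM). Likewise Nrxn2 stood at 59.7 CPM in VZ-derived, 43.2 in MGE-derived 1, 33.9 in MGE-derived 2, 16.2 in Glutamatergic 1, 12.3 in CGE-derived, 6.92 in Glutamatergic 2, 6.32 in GABAergic and 3.06 in Cajal Retzius cells. On build GRCm38, Nrxn2 (ENSMUSG00000033768) lies on chromosome 19 from 6418731 to 6544169 and Nrxn3 (ENSMUSG00000066392) on chromosome 12 from 88722876 to 90334935, both on the plus strand.

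**Figure D1:**
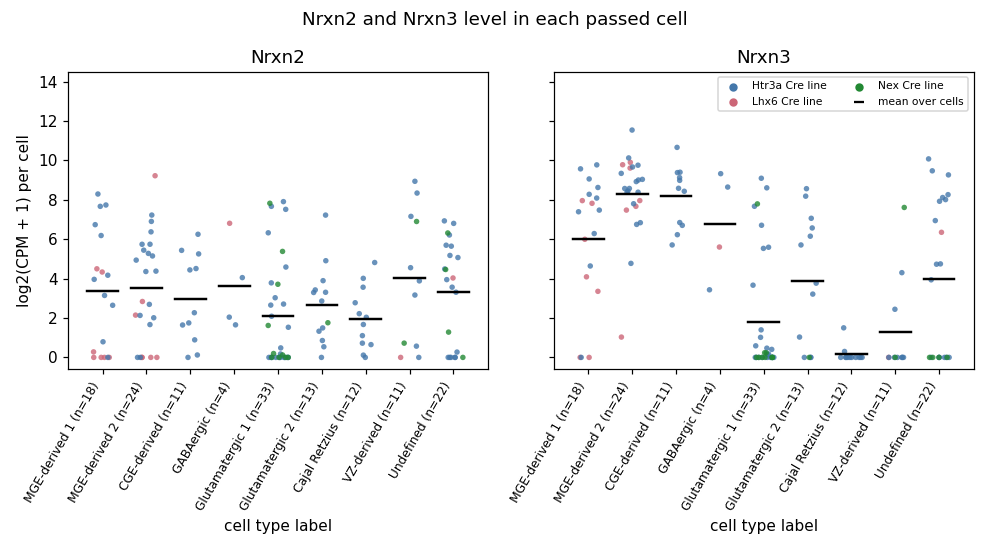
Level of Nrxn2 and Nrxn3 in each of the 148 passed cells, as log2(CPM + 1) on the vertical axis, by type label on the horizontal axis; points are cells coloured by driver line and bars are means over cells. Nrxn3 lies near 0 in 10 of the 12 Cajal Retzius cells and above 0 in all 24 MGE-derived 2 cells.

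GABAergic cells (57 cells of the MGE-derived, CGE-derived and GABAergic labels) and glutamatergic cells (46 cells of both Glutamatergic labels) differed in neurexin level. Nrxn3 was 8.33-fold higher in GABAergic cells, at 417 CPM (415 to 419) against 50.1 (49.4 to 50.7), with a log2 difference of 5.07 (SD 2.65 and 3.23). Nrxn2 was 2.53-fold higher, at 48.2 against 19.05 CPM, with a log2 difference of 1.10, less than the spread between cells (SD 2.68 and 2.56). Not all GABAergic types had more: CGE-derived cells stood at 17.6 CPM, and cells of the GABAergic label at 6.32 without the cell of most counts. Within the Htr3a line alone the log2 differences were 1.46 for Nrxn2 and 5.12 for Nrxn3.

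Genes of GABA synthesis and of interneuron fate were high in GABAergic cells, and genes of cortical projection neurons were high in glutamatergic cells. All 9 measured GABAergic neuron markers were higher by at least 1 on the log2 scale (list median 6.12). They included Gad1, an enzyme of GABA synthesis (678 against 14.7 CPM, 55 of 57 against 7 of 46 cells), and Gad2 (383 CPM against 3 counts in all, 0.00137 to 0.0193 CPM). Of 12 MGE interneuron markers 10 were higher (median 4.10), with Nxph1, a secreted neurexin ligand, in 37 of 57 against 6 of 46 cells and the receptor gene Erbb4 in 47 of 57 against 3 of 46. Of 14 glutamatergic neuron markers 11 were lower (median -2.46), and of 10 deep layer genes 8 (median -2.76). Slc17a7, a vesicular glutamate transporter, stood at 0.433 CPM (95% interval 0.380 to 0.492) against 155 CPM, and the transcription factor Neurod2 was 8.11-fold lower. Arpp21 (17.9-fold), Sybu (9.89-fold) and the calcium channel gene Cacna1e (8.06-fold) were also lower in GABAergic cells. The log2 difference was -5.17 for Slc17a7 and -5.08 for Cacna1e over all lines, and -6.10 and -6.31 within the Htr3a line.

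Genes that act at synapses were split between the 2 classes. Of 33 other synaptic adhesion molecules 11 were lower and 2 higher in GABAergic cells (median -0.49, percentile 0.380 of 10000 random lists matched on expression; -0.25 and percentile 4.82 by summed counts, inside the random range). Cdh13 was 3.47-fold lower (log2 difference -2.88, and -3.77 within the Htr3a line) and Flrt2 2.72-fold higher. Among 24 neurexin ligands and partners 7 were lower and 4 higher (median -0.23, percentile 16.9; 0.09 by summed counts), with Nlgn1 12.4-fold lower, at 8.94 against 111 CPM. Among 26 RNA-binding splicing regulators 3 were higher and 6 lower (median -0.09, percentile 47.3); Qk was 4.02-fold higher, Khdrbs1 (SAM68) 2.498-fold higher and Khdrbs2 (SLM1) 1.85-fold lower. Of 13 ionotropic glutamate receptor genes 6 were higher (median 0.43), such as Gria4 (6.08-fold) and Grik1 (6.97-fold), while Gria2 was 3.34-fold lower. The calcium channel subunit gene Cacna2d1 was 24.8-fold lower and the potassium channel gene Kcnc2 8.39-fold higher; the 20 voltage-gated channel genes had a median of -0.54 (percentile 0.510). Medians of the other lists were 2.06 for CGE interneuron markers, 0.48 for proliferation genes and 0.42 for ventricular zone progenitor markers, all outside the random range. By summed counts the last 2 were 2.11 (percentile 99.9) and 1.27 (percentile 99.7), also outside it. Cajal-Retzius cell markers had 0.29 (higher at percentile 98.9 by summed counts, outside the random range). Microglia markers had 0.23 (1.46 and percentile 99.7 by summed counts, outside it). Further medians were 0.18 for astrocyte markers, 0.17 for intermediate progenitor markers and 0.01 for oligodendrocyte lineage markers. They were -0.18 for erythrocyte genes, -0.34 for presynaptic release genes, -0.42 for pan-neuronal markers, -0.48 for GABA-A receptors and chloride transporters, -0.67 for immediate early and heat shock genes, -0.52 for upper layer genes (0.24 within the Htr3a line) and -0.48 for migration and guidance receptors (0.10 by summed counts). The mean over the list had the other sign for astrocyte markers (-0.31), oligodendrocyte lineage markers (-0.03), erythrocyte genes (0.01) and upper layer genes (0.00), so these lists show no direction. Of the endothelial and mural cell markers only 2 were counted, too few for a median. In simulated data with no difference between groups, genes were named by the rule apart from its condition on the cell of highest level. They reached log2 differences of 2.18 and -2.36, and all 20 genes named in this comparison lay beyond these values. Type labels probably rest on expression of the same cells, so genes that part the labels may pass such values for that reason. Here and in the comparisons of type labels below, simulated values describe the spread between cells and support no label. The median difference over all genes was -0.02.

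MGE-derived and CGE-derived cells, 42 and 11, are interneurons of different birthplaces by their labels. Lhx6 was high in the former, at 941 against 1.69 CPM (42 of 42 against 3 of 11 cells), and so were Sst, which encodes somatostatin (152-fold), Nxph1 (464-fold) and the chromatin organiser Satb1 (36.9-fold). Adarb2 was high in CGE-derived cells, at 1214 against 12.7 CPM (11 of 11 against 8 of 42 cells), as were Htr3a (31.4-fold) and the transcription factor genes Prox1 (72.9-fold) and Sp8 (38.5-fold). Nrxn3 had a log2 difference of -0.86 (SD 2.87 and 1.57) and Nrxn2 of 0.48 (SD 2.85 and 2.27), which was 1.71 by summed counts.

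Of 12 MGE interneuron markers 7 were higher in MGE-derived cells (median 3.66), and of 11 CGE interneuron markers 8 were lower (median -3.02). GABAergic neuron markers were mostly lower in MGE-derived cells, 6 of 9 (median -1.37, percentile 0.0600; -0.44 and percentile 3.59 by summed counts, inside the random range); Dlx2 was 2.24-fold lower and Dlx1 1.64-fold lower. Of 13 ionotropic glutamate receptor genes 7 were higher in MGE-derived cells (median 1.09, percentile 99.1). Among them Gria1 was 4.02-fold higher (log2 difference 4.81, and 5.46 without CGE-derived cell 11). Cdh13 was 18.2-fold higher and the calcium pump gene Atp2b1 22.3-fold higher. The splicing repressor Ptbp1 was 3.75-fold lower. The immediate early gene Fos was seen in 23 of 42 MGE-derived cells and in 0 of 11 CGE-derived cells. Microglia markers had a median of 0.84 (percentile 96.1, inside the random range; 5.85 and percentile 100 by summed counts); within the Htr3a line they summed to 1130.5 CPM in MGE-derived 1, 1659 in MGE-derived 2 and 18.6 in CGE-derived cells. Few cells carried these sums: 1 of 11, 5 of 17 and 2 of 11 cells held at least 3 of the genes at 10 or more counts, and the medians per cell were 0, 3.16 and 0 CPM. All 11 CGE-derived cells came from the Htr3a line; within that line the log2 differences were 1.38 for Nrxn2, -0.15 for Nrxn3, 7.57 for Lhx6, 5.09 for Sst (6.16 over all lines), -9.33 for Adarb2, -8.09 for Htr3a (-8.69 over all lines) and -2.22 for Dlx2 (-3.25 over all lines). Genes named in simulated data with no difference reached 4.003 and -4.54; all 10 named genes higher in MGE-derived cells and 8 of the 10 higher in CGE-derived cells (not Sp8) lay beyond that, and the median over all genes was 0.22.

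The MGE-derived label is split into 1 (18 cells) and 2 (24 cells). Sox6, a transcription factor gene of MGE interneurons, was lower in MGE-derived 1 cells, at 37.0 against 174 CPM (7 of 18 against 24 of 24 cells), with a log2 difference of -5.55 (SD 2.61 and 1.69) that was alike in the Htr3a line (-5.47) and the Lhx6 line (-5.75). Fbxo3, which encodes a part of a ubiquitin ligase, was 10.1-fold higher in MGE-derived 1 cells (17 of 18 against 13 of 24 cells), and the difference was 3.08 in the Htr3a line and 8.36 in the Lhx6 line. Nrxn3 was 1.77-fold lower in MGE-derived 1 cells, with log2 differences of -2.28 (SD 3.30 and 2.07) over both lines, -1.39 in the Htr3a line and -3.46 in the Lhx6 line. Nrxn2 differed by -0.15 (SD 3.05 and 2.75), less than the spread between cells, at 0.55 in the Htr3a line and -0.73 in the Lhx6 line. The sign in the Lhx6 line depends on MGE-derived 2 cell 8. Its log2(CPM + 1) was 9.23, where the next of the 7 cells had 2.84 and their median was 0.

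Of 12 MGE interneuron markers 5 were lower in MGE-derived 1 cells and 0 higher (median -0.53, percentile 50.1), with Nxph1 1.85-fold lower and Satb1 1.44-fold lower (log2 difference -1.66 in the Htr3a line and -5.90 in the Lhx6 line). Of 26 splicing regulators 14 were lower and 0 higher (median -1.05, percentile 3.28; -0.45 and percentile 1.41 by summed counts), such as Celf5 (3.15-fold; -3.37 in the Htr3a line and -2.09 in the Lhx6 line); the median was 0.40 in the Lhx6 line alone. Microglia markers were lower as well (5 of 8, median -1.13), though inside the random range by summed counts (-0.94, percentile 19.1). Cells labelled MGE-derived 1 held fewer genes (median 4563) than those labelled MGE-derived 2 (median 5493.5), and the median difference over all genes was -0.39. Genes named in simulated data with no difference reached 4.01 and -4.06; only Fbxo3 lay beyond the former and only Sox6, Ing4 and Pdha1 beyond the latter, and Ing4 shares 46.7% of its sequence stretches with other transcripts.

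Glutamatergic 1 (33 cells) and Glutamatergic 2 (13 cells) are labels for which no layer or region is given. Among single genes lower in Glutamatergic 1 cells were Nrp1, a semaphorin receptor, 7.59-fold (7 of 33 against 12 of 13 cells), the semaphorin Sema4d 60.6-fold (6 of 33 against 11 of 13), and the transcription factor gene Neurod1 3.09-fold (8 of 33 against 13 of 13). The cadherin gene Cdh10 was 7.88-fold higher in Glutamatergic 1 cells (22 of 33 against 4 of 13). Immediate early and heat shock genes were low in Glutamatergic 1 cells, 8 of 11 on the list (median -2.32, but -0.74 and inside the random range among cells with like numbers of genes), with Arc, an activity-regulated gene, at 3.02 CPM (95% interval 2.82 to 3.22) against 66.9 CPM. Of the Glutamatergic 1 cells 10 came from the Nex line, of the Glutamatergic 2 cells 1, and within the Htr3a line the log2 differences were -6.73 for Neurod1 (-5.67 over all lines) and -6.03 for Sema4d (-5.39). Nrxn2 and Nrxn3 differed by less than the spread between cells. Their log2 differences were -0.58 (SD 2.77 and 1.99) and -2.07 (SD 3.03 and 3.36), where the median over all genes was -0.97. By summed counts Nrxn3 differed by -0.45. Nrxn2 was higher by summed counts (22.2 against 13.3 CPM) and among cells with like numbers of genes (0.42).

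All 16 presynaptic release genes were lower in Glutamatergic 1 cells (median -2.12, percentile 0.240), for example Syn1 (2.35-fold) and Pclo (1.67-fold). So were 10 of 12 genes of GABA-A receptors and chloride transporters (median -2.61, percentile 0), and 14 of 20 voltage-gated channel genes (median -1.76, percentile 2.76). These counts rest on log2 differences, and by summed counts the presynaptic release gene Syt4 was higher (0.37). Glutamatergic 1 cells held fewer genes (median 4954) than Glutamatergic 2 cells (median 7585), and the median over all genes was -0.97. By summed counts, where that median was -0.07, the lists' medians were -0.56 for presynaptic genes (percentile 0.0100), -1.23 for immediate early genes (0.0200), -0.58 for GABA-A receptors (3.59) and -0.15 for voltage-gated channels (32.3), the last 2 inside the range of matched random lists. Among cells of both labels with like numbers of genes (10 against 12, medians still 6772 against 7583, median over all genes -0.26), the presynaptic median was -0.92 (percentile 0.550) and that of voltage-gated channels -1.19 (0.140), both outside the random range. There the medians of GABA-A receptors (-0.88, percentile 4.83) and immediate early and heat shock genes (-0.74, percentile 6.90) lay inside it. All 10 genes named as lower lay beyond the simulated log2 difference of -4.62, and none of the 10 named as higher lay beyond 4.12. The simulated groups did not carry the real difference in genes per cell, so this does not separate these genes from fewer genes detected. Nrp1 stood at -6.40 and, without Glutamatergic 2 cell 13, at -7.01.

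Cajal Retzius cells (12) were set against the 46 glutamatergic cells. Reln, which encodes the secreted protein reelin, reached 10152 CPM against 43.5 and was counted in 12 of 12 against 18 of 46 cells. The chemokine gene Cxcl12 was 51.3-fold higher, the secreted factor gene Ndnf 397-fold, Calb2, which encodes calretinin, 48.6-fold, and the glutamate transporter gene Slc17a6 14.4-fold. Slc17a7 was seen in 0 of 12 against 38 of 46 cells, at least 8069-fold lower. Nrxn3 was 557-fold lower (log2 difference -2.23, SD 0.43 and 3.23), a fold that rests on 14 counts, 12 of them from cell 7, and is larger without that cell, while Nrxn2 (-0.29, SD 1.57 and 2.56) differed by less than the spread between cells; by summed counts it was lower, at 5.72 against 19.05 CPM (log2 ratio -1.58), and the log2 difference was -1.01 against all other typed cells.

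Of 12 Cajal-Retzius cell markers 10 were higher (median 4.58). Markers of interneurons were higher too: 6 of 10 MGE interneuron markers, with 2 lower (median 1.14, percentile 99.95, and -1.69 against all other typed cells; 4.02 and percentile 100 by summed counts), and 5 of 9 CGE interneuron markers (median 1.07, percentile 97.4, inside the random range; 2.67 and percentile 100 by summed counts). Of 32 other synaptic adhesion molecules 16 were lower and 7 higher (median -0.93, percentile 0): Cadm1 was 56.6-fold lower and Cadm2 11.2-fold, and Cdh13 stood at 0.0257 CPM (95% interval 0.00699 to 0.0657) against 523 CPM. Partners of neurexins went both ways, 8 of 23 higher and 6 lower (median 0.72, and 0.03 without Cajal Retzius cell 3). Nlgn1, a postsynaptic partner, was counted in 0 of 12 against 35 of 46 cells (at least 5778-fold lower), whereas Clstn2 (7.92-fold), Clstn1 (7.11-fold) and Car10 (36.1-fold) were higher. Of 26 splicing regulators 8 were higher and 9 lower (median -0.05, percentile 0.0600); Rbfox1 was 33.3-fold lower, Rbfox3 9.07-fold and Celf2 6.06-fold. Among receptor genes Gabra5 was 69.2-fold lower and Grin2b 10.8-fold lower. The proliferation gene Cenpf was 2294-fold higher (log2 difference 8.32, and 9.09 without Cajal Retzius cell 3), at 613 CPM; Mki67 and Top2a, looked at only after that value was seen, were counted in 1 of 12 and 3 of 12 cells. All 12 cells came from the Htr3a line, in which the differences were 11.37 for Reln, -2.75 for Nrxn3, 7.71 for Slc17a6 (6.94 over all lines) and -6.26 for Slc17a7 (-5.33 over all lines). All 20 named genes lay beyond the simulated 3.80 and -3.86, which is no independent support for the label, and the median over all genes was 0.51.

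VZ-derived cells (11) held Reln at 653 CPM against 43.5 in the 46 glutamatergic cells (8 of 11 against 18 of 46 cells), a log2 difference of 4.33 that was 3.67 without VZ-derived cell 2 (inside the simulated range given below), 4.93 without VZ-derived cell 1, and 5.40 within the Htr3a line. The 5 Cajal-Retzius cell markers counted, of which Reln is a member, had a median of 0.77 (percentile 99). By summed counts it was 1.67 (percentile 99.5), and the median of 0.77 was 0.05 without VZ-derived cell 2. The transcription factor genes Pou3f3 (16.4-fold) and Pou3f1 (10.6-fold) and the adhesion gene Tenm4 (3.65-fold) were higher. Slc17a7 (23.3-fold) and Igsf21 (13.99-fold), a neurexin partner, were lower. Neurod6 was counted in 10 of 11 VZ-derived cells at 881 CPM, near the 683 CPM of glutamatergic cells (log2 difference 0.80, and 1.61 without VZ-derived cell 8). Nrxn2 was 4.89-fold higher (log2 difference 1.76, SD 3.42 and 2.56), and Nrxn3 (-1.08, SD 2.52 and 3.23) was lower, both by less than the spread between cells. Nrxn3 was -1.71 without VZ-derived cell 11 and -2.05 in the Htr3a line.

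Of 10 upper layer genes 5 were higher and 2 lower (median 0.95, percentile 99.9; 1.30 and percentile 99.97 by summed counts), with Cux1 2.93-fold and Pou3f2 2.23-fold higher. Deep layer genes were higher as well, 4 of 10 with 2 lower (median 0.73, percentile 98.1; 0.40 and percentile 93.6 by summed counts), and glutamatergic neuron markers had a median of 0.70 (percentile 99.2; 0.39 and percentile 96.2 by summed counts); by summed counts both lay inside the random range. Of 7 ventricular zone progenitor markers 0 were higher and 1 lower by at least 1 (median 0.39, and -0.21 without VZ-derived cell 9; 0.92 and percentile 97.9 by summed counts, above the random range); Pax6 and Sox2, chosen after their values were seen, were counted in 2 of 11 and 1 of 11 cells. Only 3 proliferation genes were counted, with a median of 1.56 (0.97 without VZ-derived cell 8), among them Ccnd2 (2.54-fold higher). Of 20 voltage-gated channel genes 5 were lower and 1 higher (median -0.69, percentile 0.300), and the receptor gene Gria1 was 9.47-fold lower. In simulated data with no difference the named genes reached 4.29 and -3.99; Reln alone lay beyond that, and not without VZ-derived cell 2, so single genes of this comparison are weakly separated from the spread between cells.

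Among MGE-derived cells, 14 of the Lhx6 line were set against 28 of the Htr3a line, while animals go with the line and library batches are not named. Labels MGE-derived 1 and 2 were pooled, at 7 and 7 cells against 11 and 17, so their mix was not held fixed. Lhx6 was 2.27-fold higher in the Lhx6 line, at 1625 against 715 CPM, and Sst 3.01-fold (log2 difference 3.22, 3.90 without MGE-derived 1 cell 3, and 1.46 among cells with like numbers of genes). Htr3a was seen in 0 of 14 against 10 of 28 cells. Single genes lower in the Lhx6 line included the cyclin gene Ccnd2 64.3-fold (log2 difference -2.96, and -0.89 among cells with like numbers of genes), the transcription factor genes Sox11 2.92-fold and Dlx2 4.09-fold, and the chemokine receptor gene Ackr3 15.4-fold (2 of 14 against 15 of 28 cells). Nrxn3 differed by -2.14, less than the spread between cells (SD 3.57 and 2.18), and by -0.79 by summed counts. Nrxn2 differed by -2.67, near that spread (SD 2.75 and 2.49), with a count in 6 of 14 against 25 of 28 cells. Its summed levels were 57.4 against 60.8 CPM, but MGE-derived 2 cell 8 held 4930 of the 5301 counts of the Lhx6 line cells, and without it their level was 4.41 CPM (95% interval 3.97 to 4.88).

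Of 16 presynaptic release genes 7 were higher in the Lhx6 line and 3 lower (median 0.91, percentile 99.9; 0.38 and percentile 92.8 by summed counts, inside the random range), and the synaptophysin gene Syp was 3.65-fold higher (14 of 14 against 21 of 28 cells). Of 12 genes of GABA-A receptors and chloride transporters 4 were higher and 0 lower (median 0.60). Splicing regulators were lower, 14 of 26 (median -1.18, percentile 0.0300), such as Celf1 (2.45-fold) and Elavl1 (2.37-fold), with Khdrbs3 (SLM2) 7.18-fold higher; without Htr3a line cells holding microglia genes the median was -0.69, and among cells with like numbers of genes -0.48. All 8 microglia markers were lower (median -1.75): C1qb stood at 0.0433 CPM (95% interval 0.0118 to 0.111) against 509 CPM, the latter from 7 of 28 cells. Lhx6 line cells held fewer genes (median 4581.5 against 5493.5), and among cells with like numbers of genes (14 against 14) the microglia median was -0.000189, but 0 of the 6 Htr3a line cells holding microglia genes lay in that range. By summed counts the microglia median was -7.10 (percentile 0). Of 10 proliferation genes 4 were lower (median -0.90, and -0.29 without Htr3a line cells holding microglia genes). Erythrocyte genes were higher (3 of 6, median 0.97), with Hba-a1 3.59-fold.

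The mitochondrial genes mt-Co3 (12.7-fold) and mt-Atp6 (11.8-fold) were higher in MGE-derived cells of the Lhx6 line, in 14 of 14 cells each. These values are uncertain, since 99.9% of the 50-base stretches of mt-Co3 and 99.5% of those of mt-Atp6 also occur in annotated nuclear transcripts. Ribosomal RNA took a median of 0.118% of counts in these Lhx6 line cells against 0.613% in the Htr3a line cells. Genes named in simulated data with no difference reached 4.34 and -3.66. Of the 10 named as higher only Ranbp6 (4.50) lay beyond that. All 10 named as lower did, led by C9orf72 (-4.62) and the kinesin gene Kif2a (-4.54). The simulated groups did not carry the real difference in genes per cell, so this does not separate these genes from fewer genes detected in the Lhx6 line.

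Among Glutamatergic 1 cells, 10 of the Nex line were set against 23 of the Htr3a line. The Nex line cells held upper layer genes, those of neurons that connect cortical areas, at higher levels: Rorb stood at 255 CPM against 0.4662 CPM (95% interval 0.380 to 0.566) and Inhba was 12.8-fold higher. Deep layer genes were lower: Fezf2, a determinant of subcortical projection neurons, was 29.2-fold lower (1 of 10 against 16 of 23 cells; log2 difference -4.43, and -5.01 without Glutamatergic 1 cell 29), and Bcl11b 5.53-fold (2 of 10 against 20 of 23; -4.16, and -5.03 without cell 25). The growth factor gene Ptn was 21.6-fold higher (10 of 10 against 7 of 23 cells), the polysialic acid enzyme gene St8sia2 23.7-fold, and Zcchc12 was seen in 0 of 10 against 16 of 23 cells. Nrxn2 and Nrxn3 differed by less than the spread between cells, at -0.31 (SD 2.81 and 2.81) for Nrxn2 (0.58 among cells with like numbers of genes) and -1.40 (SD 2.45 and 3.21) for Nrxn3, with -0.97 for Nrxn2 without cell 25 and -2.17 for Nrxn3 without cell 29.

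Of 10 upper layer genes 9 were higher in the Nex line and 0 lower (median 2.30), and of 10 deep layer genes 6 were lower and 1 higher (median -2.59; -0.85 and percentile 3.45 by summed counts, inside the random range). The exception was Ldb2, chosen after its value was seen, which was 6.40-fold higher. The median of the upper minus that of the deep layer genes was 4.89, where pairs of matched random lists gave -1.20 to 1.32. Of 32 other synaptic adhesion molecules 11 were higher and 5 lower (median 0.61, percentile 99.9), with Slitrk4 2.48-fold higher and Tenm2 5.54-fold lower. Of 16 presynaptic release genes 6 were higher (median 0.65, percentile 98.2; 0.38 and percentile 96.9 by summed counts, inside the random range), such as Stx1a (2.89-fold), while Vamp2 was 3.03-fold lower. Slc17a6 was 22.5-fold higher, while Slc17a7 was lower, at 18.0 against 156 CPM (4 of 10 against 21 of 23 cells). Microglia markers had a median of -0.27 (0.12 with 1 cell left out), and of -3.87 and percentile 1.17 by summed counts, outside the random range. Erythrocyte genes were lower (4 of 5, median -2.28), with Hba-a1 at 0.918 CPM (95% interval 0.717 to 1.16) against 64.1 CPM. Genes named in simulated data with no difference reached 4.89 and -4.91; all 10 named as higher and 7 of the 10 named as lower (not Sparcl1, Abca8a and Nae1) lay beyond that.

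**Figure D2:**
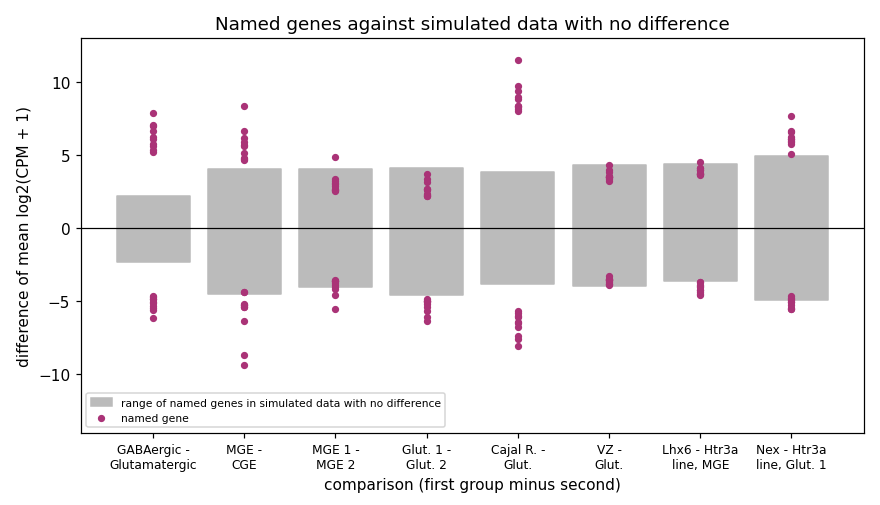
Difference of mean log2(CPM + 1) of the genes named by the rule (points) in 8 comparisons, against simulated data (grey bars). Bars span the range of named genes in simulated data with no difference, which did not carry the real difference in genes per cell. All points of the GABAergic and Cajal Retzius comparisons with Glutamatergic cells lie outside the bars, and 1 of 20 points of the VZ-derived comparison does. Type labels probably rest on the same cells' expression, so points outside the bars are no independent support for a label.

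The 3 lines gave different mixtures of types. Of 114 passed Htr3a line cells 23 were Glutamatergic 1 (20.2%, exact Clopper-Pearson 95% interval 13.2 to 28.7), 17 MGE-derived 2 (14.9%), 17 Undefined (14.9%), 12 Glutamatergic 2 (10.5%), 12 Cajal Retzius (10.5%), 11 MGE-derived 1 (9.65%), 11 CGE-derived (9.65%), 8 VZ-derived (7.02%) and 3 GABAergic (2.63%). Of 17 Lhx6 line cells 7 were MGE-derived 1 (41.2%, 18.4 to 67.1) and 7 MGE-derived 2, and none was Glutamatergic, CGE-derived or Cajal Retzius, which allows a share of each of up to 17.6%. Of 17 Nex line cells 10 were Glutamatergic 1 (58.8%, 32.9 to 81.6), 4 Undefined (23.5%) and 2 VZ-derived (11.8%). The driver genes themselves did not part the lines fully. Neurod6 was counted in 16 of 17 Nex line cells (981 CPM), 66 of 114 Htr3a line cells (359 CPM) and 5 of 17 Lhx6 line cells (344 CPM). Htr3a was counted in 50 of 114 Htr3a line cells (212 CPM), 1 of 17 Lhx6 line cells and 1 of 17 Nex line cells. Lhx6 was counted in 15 of 17 Lhx6 line cells (1326 CPM), 49 of 114 Htr3a line cells (208 CPM) and 0 of 17 Nex line cells.

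The 14 cells that failed quality control held 122 to 13277123 counts (median 3996324) in 118 to 5492 genes (median 2032.5). They made up 5 of 22 Lhx6 line cells (22.7%, 7.82 to 45.4), 8 of 122 Htr3a line cells (6.56%, 2.87 to 12.5) and 1 of 18 Nex line cells (5.56%, 0.141 to 27.3). Of the failed cells 12 of 14 held a count of the neuronal tubulin gene Tubb3, against all 22 Undefined passed cells.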

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

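Tests on mitochondrial genes (the share of sequence found in nuclear genes, and the level of genes with little such sequence), the layer values among cells with like numbers of genes and the second microglia list by summed counts were chosen only after the results were seen; the second microglia list, the thinned layer values and the test on nuclear genes with shared sequence were set before.

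Some mitochondrial genes were higher in the Lhx6 line than in the Htr3a line, over all passed cells: mt-Co3 stood at 1163 against 44.2 CPM (26.3-fold), mt-Atp6 at 1157 against 46.4 (24.9-fold) and mt-Co2 at 482 against 25.6 (18.8-fold), while mt-Co1 was 1.47-fold and mt-Cytb 1.31-fold higher. More mitochondrial RNA in the Lhx6 line is argued against, since the median log2 ratio of the 8 genes that share less than 50% of their sequence with nuclear transcripts was 0.31. Reads shared with nuclear copies are a candidate explanation, since the median of the 7 genes that share at least 50% lay 3.49 above that of the others. The best matching nuclear genes of these 7 all lie on chromosome 1, from 24611535 to 24616197. Outside the split fell mt-Atp8 (23.2-fold, no shared annotated sequence) and mt-Co1 and mt-Nd4 (51.1% and 62.2% shared, 1.47- and 1.35-fold). These genes cannot decide the matter. Nuclear copies of mt-Atp8 outside annotated transcripts were not searched for, and mt-Co1 and mt-Nd4 also hold unshared sequence. Whether shared reads were counted differently in nuclear genes too stays open: 172 such genes in MGE-derived cells had a median difference of 0.01, at percentile 100 of matched random lists (-0.25 to -0.10) and so past the limit set beforehand, but 19 were higher and 23 lower by at least 1. Animals go with the line. No label gives a library batch or alignment setting, so a difference in these between lines cannot be told apart from the line itself. A biological difference between the lines was not tested.

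Microglia markers were lower in MGE-derived cells of the Lhx6 line than in those of the Htr3a line. RNA of microglia taken up with Htr3a line cells may account for it. A second list of 10 genes, written beforehand (such as Ctss, Trem2, Tmem119, Laptm5, Fcrls, Siglech, Ly86, Lgmn and Fcer1g), had a median of -1.42. Ctss stood at 0.0974 CPM in the Lhx6 line against 297 in the Htr3a line. The second list shows that the difference reaches further microglial genes. It cannot tell uptake from any other source of microglial RNA, since such genes would move together in each case. At least 3 microglia genes had 10 or more counts in 26 of 114 Htr3a line cells, 0 of 17 Lhx6 line cells and 1 of 17 Nex line cells. Whether fewer detected genes in the Lhx6 line are the whole cause stays open. By summed counts the median of the second list was -5.88, where matched random lists gave -1.95 to 1.07, past the limit set for it. That test was chosen after the results were seen, and the first list stood at -7.10 by summed counts. Since such genes move together, the second list could hardly differ, so it cannot decide. Among cells with like numbers of genes nothing could be tested, because 0 of the 6 Htr3a line MGE-derived cells with such genes lay in that range. A difference between the lines in the embryos themselves was not tested.

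Upper layer genes were higher and deep layer genes lower in Nex line than in Htr3a line Glutamatergic 1 cells, by 4.89 between the list medians. A difference in total counts is argued against, since the value was 5.13 after cells were thinned to 1 total, and so is the number of genes detected, since it was 4.61 among cells with like numbers of genes. By summed counts the deep layer median was -0.85, inside the range of matched random lists. It may be that the lines label neurons of different layers under the same type label, a hypothesis found and examined on the same cells. No label names a batch, so a batch that differs by line stays open.

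Total counts, number of genes, Nrxn2 and Nrxn3 in each of 5 groups of 4 to 10 cells made 20 sets of values. In these, 3 values stood farther from the next cell than Dixon's 95% critical value allows. Its rate of about 1 in 20 by chance holds for normal values and not for neurexin levels with many counts of 0. In the sets of the first 2 values below the median was 0. Log2(CPM + 1) of Nrxn3 was 7.80 in Nex line cell 29 of Glutamatergic 1, where the next was 0.24. Nrxn2 was 9.23 in Lhx6 line cell 8 of MGE-derived 2, where the next was 2.84. Nrxn3 was 1.03 in Lhx6 line cell 1 of MGE-derived 2, where the next was 7.48. Of 347 genes looked at in the MGE-derived labels, 0 separated the cells in opposite directions in the 2 lines. A gene separated the cells only where every cell of 1 label lay above every cell of the other. Cells with a count of 0 make this rare, so the result does not show that the lines agree. The Nrxn2 differences given above had opposite signs in the 2 lines, but the sign in the Lhx6 line depends on cell 8 of MGE-derived 2.

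The 22 passed cells labelled Undefined were left out of the comparisons between typed cells and held markers of several types. They were part of the shares of types by line, the values over whole lines and the passed cells. In CPM of summed counts they held Nrxn2 at 26.95, Nrxn3 at 181, Gad1 at 72.3, Gad2 at 38.8, Neurod6 at 637, Neurod2 at 126, Slc17a7 at 30.1, Reln at 884, Lhx6 at 152, Adarb2 at 74.3, Pax6 at 19.7, Tubb3 at 1592 and Stmn2 at 2247. The 14 failed cells held Nrxn2 at 8.77, Nrxn3 at 155, Gad1 at 440.2, Gad2 at 628, Neurod6 at 338, Neurod2 at 89.5, Slc17a7 at 8.60, Reln at 39.2, Lhx6 at 689, Tubb3 at 942 and Stmn2 at 1172 CPM.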

How the results depend on the processing

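Each of 614 values was recomputed under the alternatives that apply to it, 6232 values in all. The alternatives that counted a cell from 10 counts, kept cells with like numbers of genes, left out cells with microglia genes or left out ribosomal RNA were chosen after the data were seen. Of these values 4800 stayed within a factor of 1.5, 1424 moved by more and 8 of log2 size 1 or more changed sign; smaller values that changed sign are counted with the others. Effective library sizes from edgeR (560 values), leaving out ribosomal RNA (198), the count table by symbol (145), leaving out the GABAergic label (76) and leaving out Undefined cells (15) moved none; thinning moved 9 of 596. No paired analysis was possible because the labels name no animal or litter that would pair cells. Given here are the main answers to a comparison that moved and those 8 values. Apart from the pseudocount, which shrinks differences by construction, and the scale of the authors' normalized table, the cause was not tested. A pseudocount of 10 gave for GABAergic against glutamatergic cells Nrxn3 3.25, glutamatergic markers -1.43 and GABAergic markers 3.66. For MGE-derived against CGE-derived cells it gave MGE interneuron markers 2.11 and CGE interneuron markers -1.71. For Glutamatergic 1 against 2 it gave Nrxn2 0.0278, Nrxn3 -1.02, GABA-A receptors -1.30, voltage-gated channels -0.81 and presynaptic release genes -1.38. For Cajal Retzius cells it gave Nrxn3 -1.18 and Cajal-Retzius cell markers 2.27. For VZ-derived cells it gave Nrxn2 1.11. For the Lhx6 against the Htr3a line it gave Nrxn2 -1.22, Nrxn3 -1.53 and microglia markers -1.07. For the Nex against the Htr3a line it gave Nrxn3 -0.66, upper layer genes 1.28 and deep layer genes -1.72. Summed counts weight cells by depth and take the log after cells are combined, where the main measure averages logs of single cells. Mean CPM, which weights cells alike, moved only 1 of 18 values from the CPM of summed counts (Nrxn2 and Nrxn3 by type). Summed counts gave for GABAergic against glutamatergic cells Nrxn3 3.03 and GABAergic markers 5.38. For MGE-derived against CGE-derived cells it gave Nrxn2 1.71, Nrxn3 -0.15 and CGE interneuron markers -1.22. For MGE-derived 1 against 2 it gave Nrxn3 -0.82 and splicing regulators -0.45. For Glutamatergic 1 against 2 it gave Nrxn2 0.70, Nrxn3 -0.45, Syt4 0.37, splicing regulators 0.18, GABA-A receptors -0.58, voltage-gated channels -0.15 and presynaptic release genes -0.56. For Cajal Retzius cells it gave Nrxn2 -1.58, Nrxn3 -5.55, adhesion molecules -1.88, Cajal-Retzius cell markers 5.73 and presynaptic release genes -0.16. For the Lhx6 against the Htr3a line it gave Nrxn2 -0.0826, Nrxn3 -0.79 and microglia markers -7.10. For the Nex against the Htr3a line it gave Nrxn3 -0.68, upper layer genes 3.14 and deep layer genes -0.85. Cells of the authors' normalized table had totals of 2637852.6 to 9039348.2, larger than those of CPM, and 1 was added to its values as well. That 1 weighs less there than in CPM, which widens differences by construction. The authors' normalized table gave for GABAergic against glutamatergic cells Nrxn3 6.14, glutamatergic markers -3.20 and GABAergic markers 7.76. For MGE-derived against CGE-derived cells it gave MGE interneuron markers 4.73 and CGE interneuron markers -3.83. For Cajal Retzius cells it gave Nrxn3 -3.03 and Cajal-Retzius cell markers 6.10. For the Lhx6 against the Htr3a line it gave Nrxn2 -3.81. For the Nex against the Htr3a line it gave Nrxn3 -2.04, upper layer genes 3.09 and deep layer genes -3.26. Within the Htr3a line the values were for MGE-derived against CGE-derived cells Nrxn2 1.38, Nrxn3 -0.15 and CGE interneuron markers -2.26. For MGE-derived 1 against 2 it gave Nrxn2 0.55 and Nrxn3 -1.39. For VZ-derived cells it gave Nrxn3 -2.05. Within the Lhx6 line they were for MGE-derived 1 against 2 Nrxn3 -3.46 and splicing regulators 0.40. With all other typed cells as the comparison group they were for Cajal Retzius cells Nrxn2 -1.01, Nrxn3 -4.67, Lhx6 -2.25 and MGE interneuron markers -1.69. For VZ-derived cells it gave Nrxn3 -3.36. With genes of other lists left out they were for GABAergic against glutamatergic cells glutamatergic markers -3.33. For MGE-derived against CGE-derived cells it gave CGE interneuron markers -3.61. For the Nex against the Htr3a line it gave upper layer genes 3.34. Among cells with like numbers of genes they were for Glutamatergic 1 against 2 Nrxn2 0.42, GABA-A receptors -0.88 and presynaptic release genes -0.92. For the Lhx6 against the Htr3a line it gave C1qb 0.038, C1qc 0.0594, splicing regulators -0.48 and microglia markers -0.000189. For the Nex against the Htr3a line it gave Nrxn2 0.58 and deep layer genes -1.73. Adding failed cells gave for MGE-derived against CGE-derived cells Nrxn3 -0.26. Leaving out each cell in turn gave -1.71 to -0.93 for Nrxn3 of VZ-derived cells, -0.97 to -0.048 for Nrxn2 of the Nex against the Htr3a line and -2.17 to -1.08 for Nrxn3 of the Nex against the Htr3a line. Depth limits what a single cell shows, and a count of 0 in a cell does not show absence. Thinning to 4563756 counts left out cells with fewer counts. The median number of genes in Glutamatergic 2 cells was 7585 over 13 cells before and 7426.5 over 12 cells after, a small change.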

Other observations

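Gad1 or Gad2 and Neurod2 or Neurod6, genes that usually mark different classes of neurons, were counted together in many Undefined cells, a measure chosen after the data were seen. At 10 or more counts each, both sets were present in 13 of 22 Undefined cells (59.1%, exact Clopper-Pearson 95% interval 36.4 to 79.3), in 16 of 57 GABAergic cells (28.1%, 16.97 to 41.5) and in 2 of 46 glutamatergic cells (4.35%, 0.531 to 14.8). No Undefined cell held Gad1 or Gad2 alone, and 6 of 22 held Neurod2 or Neurod6 alone. Undefined cells held Reln in 17 of 22 cells, Lhx6 in 10 and Pax6 in 10.

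Among cells of the Lhx6 line Neurod6 was counted in 5 of 17, all at 10 or more counts, and Htr3a in 1 of 17. Within MGE-derived cells of the Htr3a line, Fcrls, a gene of microglia, was counted in 9 of 28 cells and Laptm5 in 7 of 28, against 0 of 14 Lhx6 line cells for each.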
